A study of Citrus sinensis with 6 samples.

How the data were processed

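Small RNAs and degradome tags were measured in 3 kinds of Valencia sweet orange (Citrus sinensis) callus, with 1 library per callus and assay, 6 libraries in all. Per the labels, NEC is callus that does not form embryos, EC is callus that can, and E1-4 is EC sampled in weeks 1 to 4 of embryo induction and pooled. The labels state that RNA of 16 to 28 nt was selected from total RNA and ligated to adaptors at both ends for the small RNA libraries. For the degradome libraries, per the labels' protocols, polyadenylated RNA with an uncapped 5' end received a 5' adaptor. A later digestion step with the restriction enzyme MmeI, which cuts DNA, left a short tag starting at the uncapped end.

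Each deposited file lists distinct sequences with their length and a count, and the count column holds whole reads per sequence as deposited, with no normalization. The adaptor trimmer, its settings, any quality filter and any genome build are not given in the sources used here. The small RNA files held sequences of 18 to 30 nt and the degradome files sequences of 18 to 44 nt, so shorter products were not measured. No molecular identifiers were recorded, so PCR copies are not independent molecules, and every interval and detection limit below covers counting error only.

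No genome sequence or gene annotation with sequence was used. Family levels therefore rest on reference sequences written by hand before the data were examined and not checked against a database, and cover 42 families (49 references) plus 7 control families. The controls were 4 families known from Brassicaceae and 3 animal miRNAs. A tag of 18 to 24 nt was given to the family it matched best with at most 2 mismatches, a 5' end within 2 nt of the reference, and at least 18 nt compared. Names of loci came from a RefSeq gene table of the assembly DVS_A1.0, which names 129 miRNA genes and was used for names only, because the files name no build. Planned steps that needed a genome were left out. These were target genes per transcript, degradome tags per gene in fixed gene lists, origin classes of small RNAs, the genome-matched total and the removal of ribosomal and transfer RNA.

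Levels were expressed as reads per 1000000 reads in the file (RPM), computed here from the deposited counts. Shares carry exact Clopper-Pearson 95% intervals, levels exact Poisson intervals, and ratios of 2 libraries exact conditional binomial intervals. A family was called higher or lower when it had at least 100 reads in 1 of the 2 libraries, differed at least 2-fold and had an interval that left out 1. A count of 0 was taken to allow up to 3 counts, and a fold against such a library was computed against 3 counts in that library. With 1 library per group no test between conditions was possible, and no p-value is given. A call describes the pair of libraries, not the conditions.

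Degradome tags of 18 to 24 nt were merged on their first 18 nt, so that each distinct 5' end counted once with its reads. A tag was taken to start at the expected cleavage position when its first 9 nt were the exact reverse complement of miRNA nucleotides 2 to 10. The same 9-nt word at the 9 other places in the tag, and 100 shuffled copies of each miRNA, served as background. A family counted as above background when its tags at the expected position exceeded the highest other place and the 95th percentile of the shuffled copies.

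The families named in each comparison followed a rule fixed at the same stage. It took the 10 families with the largest ratio each way among those called, miR156, miR172, miR160, miR167, miR390, miR393, miR164, miR166, miR162 and miR168 whatever their value, and 2 to 4 members with the largest ratio of each list. The control families gave the background. The 7 lists were phase change, auxin response, organ and meristem transcription factors, small RNA machinery, nutrient and copper, disease resistance genes, and citrus and other less conserved families.

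Alternatives covered 5 other library totals, TMM factors over the families (edgeR 4.0.16 in R 4.3.3), the mismatch and 5' end limits, read minimums of 10 and 1000, distinct sequences in place of reads, thinning to 20188985 reads, and other word lengths and mismatches in the degradome. Counting was done in Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. The matcher was tested on simulated data, where 99.9% of 2310 planted variants returned to their own family and 0 of 200000 random 21-nt tags matched any. Simulated EC and NEC counts, drawn at the real depths with Poisson error alone, gave calls in 0% of 200 pairs without a difference. They gave calls in 54.0% of 200 pairs at 2-fold and 100% at 3-fold. No variation between libraries was simulated, so these numbers give no rate of false calls for the real comparisons.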

Results

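The series profiled 3 callus types of Valencia sweet orange to describe the small RNAs of citrus somatic embryogenesis. NEC was newly induced from epicotyl segments on medium with auxins and cytokinins. EC came from an immature ovule and had been kept for 28 years. E1-4 was EC moved to medium with 2% glycerol, which induces somatic embryos, and pooled over weeks 1 to 4. The small RNA libraries held 20188985 reads in NEC, 24062915 in EC and 23797526 in E1-4. The degradome libraries held 13180299, 10584122 and 11237030 tags in the same order. No group had a replicate, so each difference below is between 2 libraries without a replicate check, and the 95% intervals in brackets cover counting error only. Levels are in reads per 1000000 reads (RPM).

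The small RNA population of NEC was led by 21-nt reads, whereas those of EC and E1-4 were led by 24-nt reads, the class that in plants guides DNA methylation. In NEC 27.7% of reads were 21 nt and 22.1% were 24 nt. In EC the shares were 18.03% and 36.4%, and in E1-4 they were 17.1% and 43.2%. The ratio of 24-nt to 21-nt reads was 0.797 in NEC, 2.02 in EC and 2.53 in E1-4. All 95% intervals of these shares were narrower than 0.1 percentage points. EC also had a 20-nt peak of 23.2% of its reads, against 10.6% in NEC and 11.2% in E1-4. Without miRNA reads the 20-nt share was 5.21% in EC, 10.3% in NEC and 5.36% in E1-4, so that NEC had the highest. Reads of 18 and 19 nt made up 8.28% and 9.72% of NEC, and together 4.24% of EC and 5.78% of E1-4. Counted as distinct sequences, 24 nt was the largest class in each library, with 40.9% in NEC, 53.3% in EC and 47.3% in E1-4.

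**Figure D1:**
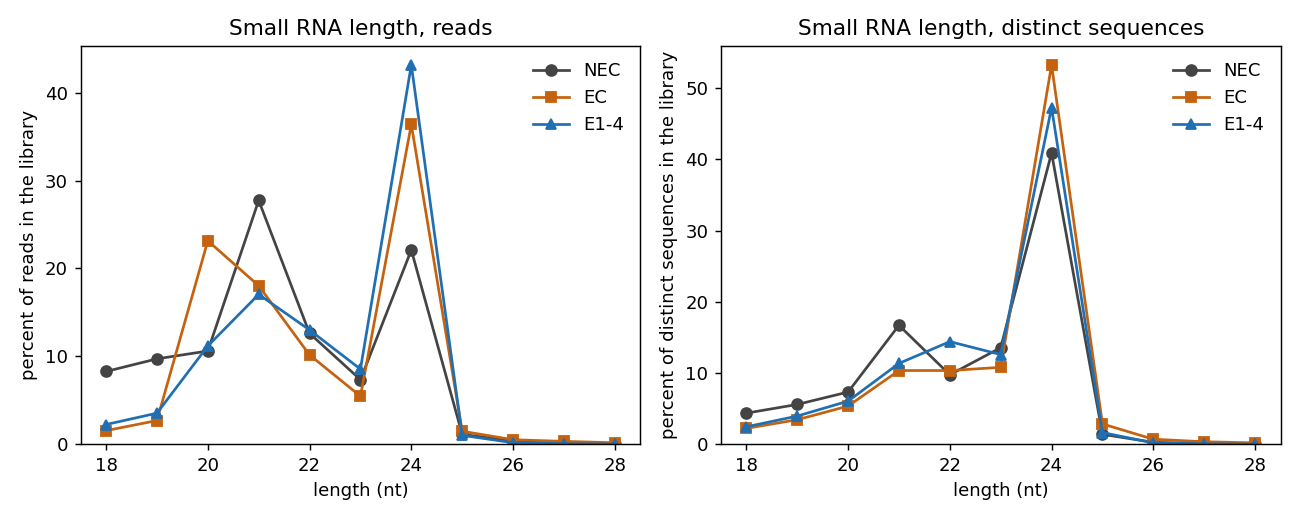
Share of reads (left) and of distinct sequences (right) by length in nt for the NEC, EC and E1-4 small RNA libraries, 1 line per library. NEC reads peak at 21 nt with 27.7%, EC and E1-4 reads at 24 nt with 36.4% and 43.2%, and distinct sequences peak at 24 nt in each library.

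The first base followed the size class. Among 24-nt reads, 48.7% began with A in NEC, 57.9% in EC and 55.9% in E1-4. Among 21-nt reads, U was the most frequent first base, with 37.1% in NEC, 45.5% in EC and 39.8% in E1-4, although by distinct sequences A led in NEC with 33.6% against 30.03% for U. These first bases are those preferred by the Argonaute proteins that load each class. Few distinct sequences were common to any pair of libraries. EC and E1-4 shared 12.8% of their union of distinct sequences, EC and NEC 9.11%, and E1-4 and NEC 7.77%. Among 24-nt sequences the shares were 16.8%, 11.3% and 10.3%. Most distinct sequences were seen once, 70.4% in NEC, 78.6% in EC and 80.8% in E1-4, and among sequences with at least 2 reads in either library the shares were 47.4%, 29.3% and 27.3%. At equal depth they were 12.3%, 9.24% and 8.003%.

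The comparison of EC with NEC asks which miRNA families mark embryogenic competence. EC was dominated by miR156, which represses SPL transcription factors and holds plants in the juvenile phase. It reached 218176 RPM in EC against 13305 in NEC, 16.4-fold higher (16.3 to 16.5), or 29.3-fold when the 5' end had to match the reference. Every measured family of the auxin list was lower in EC, under each library total tried. Of 42 families searched, 30 had enough reads, of which 5 were higher in EC, 19 lower and 6 neither.

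In the auxin response list all 5 measured members were lower in EC. miR393, which targets the auxin receptors, had 2333 reads in NEC and 0 in EC, at least 927-fold lower against 3 counts, with an exact interval from 753. Only 190 of the NEC reads began at the reference 5' end, for which the fold was at least 75.5. miR160, which targets auxin response factors, was represented by 1 read in EC and 123 in NEC, a ratio of 147 (25.8 to 5837), although 26 of the 123 and the 1 in EC had no mismatch. miR167, which also targets auxin response factors, was 78.1-fold lower (63.4 to 97.5), with an EC to NEC ratio of 0.0128. With no mismatch allowed the ratio was 0.263, on 57 of 89 reads in EC and 182 of 5835 in NEC. That rule left out the main NEC form of miR167, which had 5245 reads in NEC and 14 in EC, so the 2 ratios describe different forms. miR390, which triggers the trans-acting small RNAs of TAS3, was 8.31-fold lower (8.15 to 8.48) and those trans-acting small RNAs (tasiARF) 11.6-fold lower (9.34 to 14.5). In the phase change list miR172, which represses AP2-like genes, was 9.43-fold lower (7.72 to 11.6), opposite to miR156.

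In the nutrient and copper list 0 members were higher and 4 lower of 4 measured. miR408, which targets copper proteins such as plantacyanins, had 16401 reads in NEC and 2 in EC, a ratio of 9774 (2705 to 80714). The laccase regulator miR397 was 416-fold lower (360 to 484), and miR398, which targets a copper and zinc superoxide dismutase, 109-fold lower (83.5 to 145), on reads of which 1 of 5025 in NEC had no mismatch. miR827 was 3.04-fold lower (2.68 to 3.46), with its direction turned under TMM scaling. The organ and meristem list was split, with 2 members higher, 3 lower and 3 neither of 8. miR171, which targets GRAS transcription factors, was 83.3-fold higher in EC (60.8 to 117), on reads of which 36 of 3872 in EC had no mismatch, and miR394, which targets an F-box gene of the shoot meristem, 39.3-fold higher (27.5 to 58.0). miR169, which targets nuclear factor Y subunits, was 1057-fold lower (788 to 1456) and miR159, which targets MYB genes, 14.5-fold lower (13.0 to 16.2). miR164, a regulator of NAC boundary genes, had 211 RPM in EC and 108 in NEC, and miR166, a regulator of homeodomain leucine zipper genes, had 4805 and 2938. Both ratios were under the 2-fold limit, were called higher in EC under 4 of the 6 other totals, including TMM scaling and both totals without miR156, and turned to lower when miRNA reads were the total. With the reference 5' end only, miR166 was called higher, with a ratio of 3.94.

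In the small RNA machinery list, 2 members were higher in EC, 1 lower and 1 neither of 4. miR403, which targets an Argonaute, was 4.33-fold higher (4.21 to 4.45) and miR1515 2.28-fold higher (1.99 to 2.62), although both turned to lower with miRNA reads as the total. miR168, which targets the main miRNA-loading Argonaute, was 10.9-fold lower (10.6 to 11.3). miR162, which targets the Dicer-like enzyme of miRNAs, had 71.1 RPM in EC and 107 in NEC, and was called higher in EC under TMM scaling and lower with miRNA reads as the total. In the disease resistance list the 1 measured member, miR482, was 6.27-fold lower (5.72 to 6.88). Among the less conserved families 0 were higher, 4 lower and 2 neither of 6. miR3951 was 70.5-fold lower (61.5 to 81.3), miR3948 10.8-fold lower (8.52 to 13.9), miR3952 3.46-fold lower (3.31 to 3.61), and miR535 2.92-fold lower (2.86 to 2.98). Of the miR3948 reads, 71 of 681 in NEC and 7 of 75 in EC had no mismatch. The top-ranked miR3948 form made up 2.94% of the family in NEC and 1.33% in EC, so no single sequence carried it. With at most 1 mismatch miR535 lost its call, with a ratio of 0.647, but on only 172 of 12397 reads in EC and 223 of 30343 in NEC. The main miR535 form lay outside that limit. It made up 90.5% of the family in EC and 92.1% in NEC, at 466 and 1384 RPM. Under TMM scaling the direction of miR535 turned, and miR3952 and miR482 lost their calls, with EC to NEC ratios of 0.986 and 0.544.

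The 4 Brassicaceae control families had 0 to 3 reads in each library. TMM scaling moved every log2 ratio of EC to NEC up by 1.77, the total of miRNA reads moved it by -2.35, and the splits became 11 higher and 14 lower under TMM and 3 higher and 26 lower under the miRNA total. With 20 to 22 nt reads of no family as the total, which leaves out the 18 and 19 nt reads in which NEC was rich, the split was 8 higher and 17 lower, and NEC and EC differ also in tissue of origin, medium and age in culture.

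**Figure D2:**
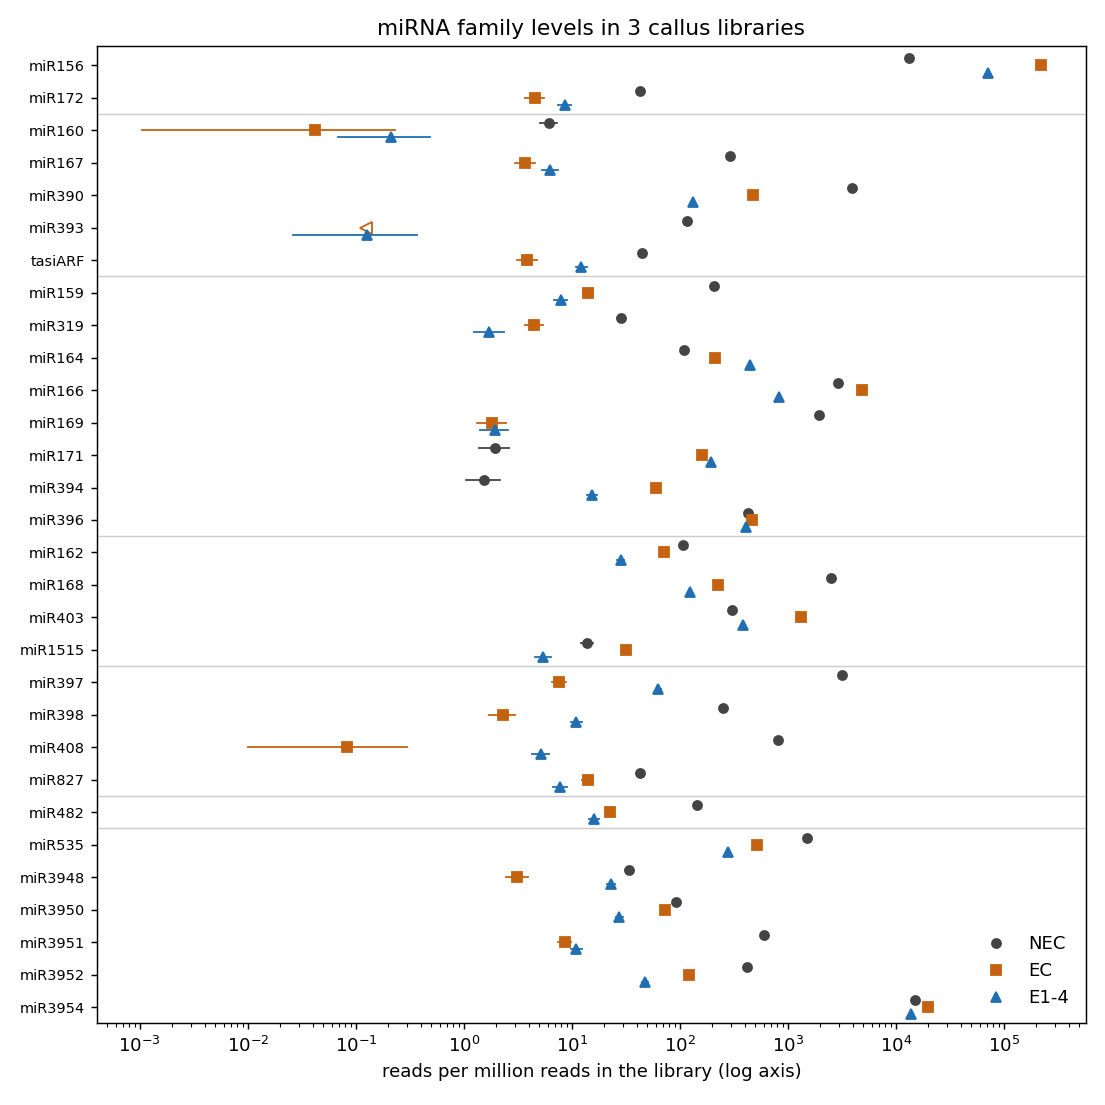
RPM (log axis) of the 30 miRNA families with at least 100 reads in a library, in NEC (circles), EC (squares) and E1-4 (triangles). Horizontal lines are 95% Poisson intervals, grey lines part the family lists, and the open marker is the limit of 3 counts for miR393 in EC. miR156 runs from 13305 in NEC to 218176 in EC, while miR167, miR390, miR393, miR397, miR398 and miR408 sit farthest right in NEC under each library total tried.

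The comparison of E1-4 with EC asks which families differ once embryogenic callus is on the medium that induces embryos. Of the copper families, miR408, miR397 and miR398 were higher in E1-4, while miR156 was lower by a fold that depended on the library total. miR408 had 123 reads in E1-4 and 2 in EC, 62.2-fold higher (16.9 to 519). miR397 was 8.32-fold higher (7.13 to 9.75) and miR398 4.82-fold higher (3.59 to 6.57), and all 3 stayed higher under each library total tried. miR156 was 3.09-fold lower (3.08 to 3.09), at 70641 RPM, and stayed lower under each library total tried. Its ratio of E1-4 to EC was 0.912 with miRNA reads as the total and 0.542 with miR156 out of that total, which ended the call in both cases. The miRNA total was itself mostly miR156, with 5249961 of 5929952 reads in EC and 1681090 of 2082778 in E1-4, so it hides much of a change in miR156. Of 27 families compared, 6 were higher in E1-4, 10 lower and 11 neither.

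In the nutrient and copper list 3 members were higher and 1, miR827, was neither, with 7.82 RPM in E1-4 and 13.96 in EC. In the auxin response list 1 member was higher, 1 lower and 1 neither of 3. tasiARF was 3.15-fold higher (2.49 to 4.03) and miR390 3.63-fold lower (3.49 to 3.78). miR167 had 6.30 RPM against 3.70, and was called higher in E1-4 under TMM and with miRNA reads as the total, with or without miR156. miR160 had 5 reads in E1-4 and 1 in EC, and miR393 had 3 and 0, too few for a comparison. In the phase change list miR172 was neither, with 8.61 RPM against 4.53, and was called higher in E1-4 under the same 3 totals, with a ratio of up to 5.36.

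The organ and meristem list had 1 member higher, 3 lower and 3 neither of 7. miR164 was 2.10-fold higher (2.03 to 2.17). miR166 was 5.85-fold lower (5.76 to 5.94), miR394 3.91-fold lower (3.49 to 4.40) and miR319, which targets TCP genes, 2.58-fold lower (1.79 to 3.80). In the small RNA machinery list 3 members were lower and 1 neither of 4. miR1515 was 5.81-fold lower (4.82 to 7.06), miR403 3.45-fold lower (3.37 to 3.54) and miR162 2.50-fold lower (2.29 to 2.74). miR168 had 123 RPM against 227. In the disease resistance list the 1 measured member, miR482, was neither, with 16.0 RPM against 22.7. Of the 6 measured less conserved families 1 was higher, 2 lower and 3 neither. miR3948 was 7.44-fold higher (5.84 to 9.60), miR3950 2.66-fold lower (2.43 to 2.91) and miR3952 2.53-fold lower (2.36 to 2.71). In E1-4 and EC, 72 of 552 and 7 of 75 miR3948 reads had no mismatch, as did 0 of 656 and 1 of 1763 miR3950 reads. No single form dominated miR3948, so what these 2 matches measure is unclear. With miRNA reads as the total, miR319, miR162, miR3950, miR3952, miR168, miR482 and miR827 turned to higher in E1-4, and miR390, miR394 and miR403 lost their calls, with ratios of 0.776, 0.720 and 0.815. The call of miR164 was lost with all reads but miR156 as the total, with a ratio of 1.77, and with 20 to 22 nt reads of no family, with 1.74. Under TMM scaling miR319, miR162, miR3950 and miR3952 lost their calls too.

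The split depended on the library total. It was 11 higher and 2 lower with miRNA reads as the total (log2 shift 1.49), 10 and 5 without miR156 in that total (0.74), 8 and 6 under TMM (0.51), and 5 and 14 with all reads but miR156 (-0.25) or with 20 to 22 nt reads of no family (-0.27).

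Against NEC, E1-4 showed 4 families higher, 22 lower and 4 neither of 30. miR171 was 99.5-fold higher (72.7 to 140), miR394 10.04-fold (367 reads against 31), miR156 5.31-fold (5.29 to 5.33; 9.61-fold with the reference 5' end only) and miR164 4.09-fold (3.91 to 4.29). All 5 auxin families were lower. miR393 had 3 reads against 2333, a ratio of 917 (313 to 4448), or 3 against 190 reads with the reference 5' end. miR167 was 45.9-fold lower (39.0 to 54.3), with a ratio of 0.340 with no mismatch, on 73 against 182 reads without the main NEC form. miR390 was 30.2-fold lower (29.1 to 31.3). miR160 was 29.0-fold lower (12.1 to 90.9), with 5 against 26 reads with no mismatch. The direction of tasiARF, 3.67-fold lower (3.21 to 4.20), turned under TMM scaling. Of the 8 organ and meristem families 3 were higher, 4 lower and 1 neither, with miR169 1000.3-fold lower (750 to 1367) and miR159 26.2-fold lower (22.7 to 30.5). All 4 measured copper and nutrient families were lower, with miR408 157-fold (132 to 189), miR397 50.04-fold (47.5 to 52.7) and miR398 22.6-fold (19.96 to 25.7), although miR827 lost its call under TMM scaling, with a ratio of 0.890. In the small RNA machinery list 0 were higher, 3 lower and 1 neither. miR168 was 20.2-fold lower (19.5 to 20.99). miR3951 was 55.1-fold lower (48.7 to 62.5), among less conserved families of which 0 were higher, 4 lower and 2 neither. Of these 4, TMM scaling turned miR3950 and ended the calls of miR535 (0.907) and miR3952 (0.553), which left miR3951. miR482 was 8.90-fold lower (7.99 to 9.93) and miR172 4.96-fold lower (4.25 to 5.80), but under TMM scaling both lost their calls, with ratios of 0.544 and 0.976. miR162, 3.75-fold lower (3.44 to 4.10), and miR166, 3.58-fold lower (3.52 to 3.63), both turned under TMM scaling, and miR166 lost its call with the reference 5' end only (0.556). TMM scaling moved every log2 ratio up by 2.27 and gave 8 higher and 12 lower.

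The degradome libraries ask where miRNAs direct cleavage, since Argonaute cuts the target opposite nucleotides 10 and 11 of the miRNA and leaves an uncapped end there. Tags at that position were most frequent for miR3951 in NEC (22460 tags), miR3952 in E1-4 (9553) and in NEC (5374), miR390 in NEC (3026), miR2111 in NEC (1601) and miR171 in E1-4 (1519), although miR2111 itself had 1 small RNA read in NEC and 0 in EC and E1-4. With a word of 10 nt that also pairs miRNA nucleotide 1, miR3951 had 1 tag in NEC, miR390 had 11 and miR2111 had 0, and none of the 3 was above background there, while miR3952 stayed above in each library with that word but not in EC with 1 mismatch. Of 42 families, 7 were above background in NEC, 4 in EC and 8 in E1-4, and 13 in at least 1 library. Of these, 1 family, miR3952, was above background in each library. None of the 7 control families was above background in any of the 3 libraries.

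Tags for miR3952, above background in each library, were 6.13-fold lower in EC than in NEC (5.67 to 6.64) and 12.8-fold higher in E1-4 than in EC (11.8 to 13.8). The size of these folds depends on the total, since 10 tags made up 9.70% of NEC, 37.2% of EC and 15.9% of E1-4. With those tags out of the total, 28 of 30 tag ratios kept their direction and an interval that left out 1. The other 2 had an interval that held 1 and then left it out. These were miR169 for EC over NEC and miR156 for E1-4 over EC, and the latter changed side, from higher to lower in E1-4. The miR3952 level itself was 418 RPM in NEC, 121 in EC and 47.7 in E1-4, so tags and level did not move together from EC to E1-4. miR390, miR3951, miR164 and miR398 were above background in NEC, with 3026, 22460, 620 and 263 tags, and within background in EC, with 40, 468, 28 and 41, so no fold is given. miR171 and miR166 were above background in E1-4, with 1519 and 269 tags, and within it in EC, with 35 and 29. With the most abundant observed sequence of the family in place of the references, miR171 was above background in EC too. The miR171 level itself was 161 RPM in EC and 192 in E1-4, and that of miR166 was lower in E1-4. In E1-4 miR164 had 168 tags, against 162 at another position, and miR398 had 0. With 1 mismatch allowed, miR164, miR166 and miR171 were not above background in any library in which they had been, by distinct tags neither were miR171 and miR398, and with the 10-nt word neither were miR166 and miR398. For miR156 the expected position held 244 tags in NEC, 474 in EC and 538 in E1-4, above background in E1-4 alone, and not there by distinct tags or with 1 mismatch. In EC another position of miR156 held 1771 tags, and with the 10-nt word miR156 was above background in NEC too. miR319 was above background in NEC and E1-4, with 175 and 102 tags, and in neither with 1 mismatch, while the 10-nt word put it above in EC. In the auxin response list 1 of 5 families, miR390, was above background in NEC, and 0 of 5 in EC and in E1-4, while the 10-nt word put miR390 and tasiARF above background in E1-4. Tags for miR160 numbered 31 in NEC and 0 in EC and E1-4, while miR393 had 22, 0 and 11, and miR167 had 0, 0 and 15. The small RNA machinery list had 0 of 4 families above background in NEC, 1 in EC, miR1515 with 228 tags but not by distinct tags or with 1 mismatch, and 0 in E1-4. By distinct tags miR1515 was above background in NEC instead, and the 10-nt word put miR403 above it in E1-4. The disease resistance list had 0 of 3 in each library, although miR482 was above background in E1-4 with the 10-nt word.

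**Figure D3:**
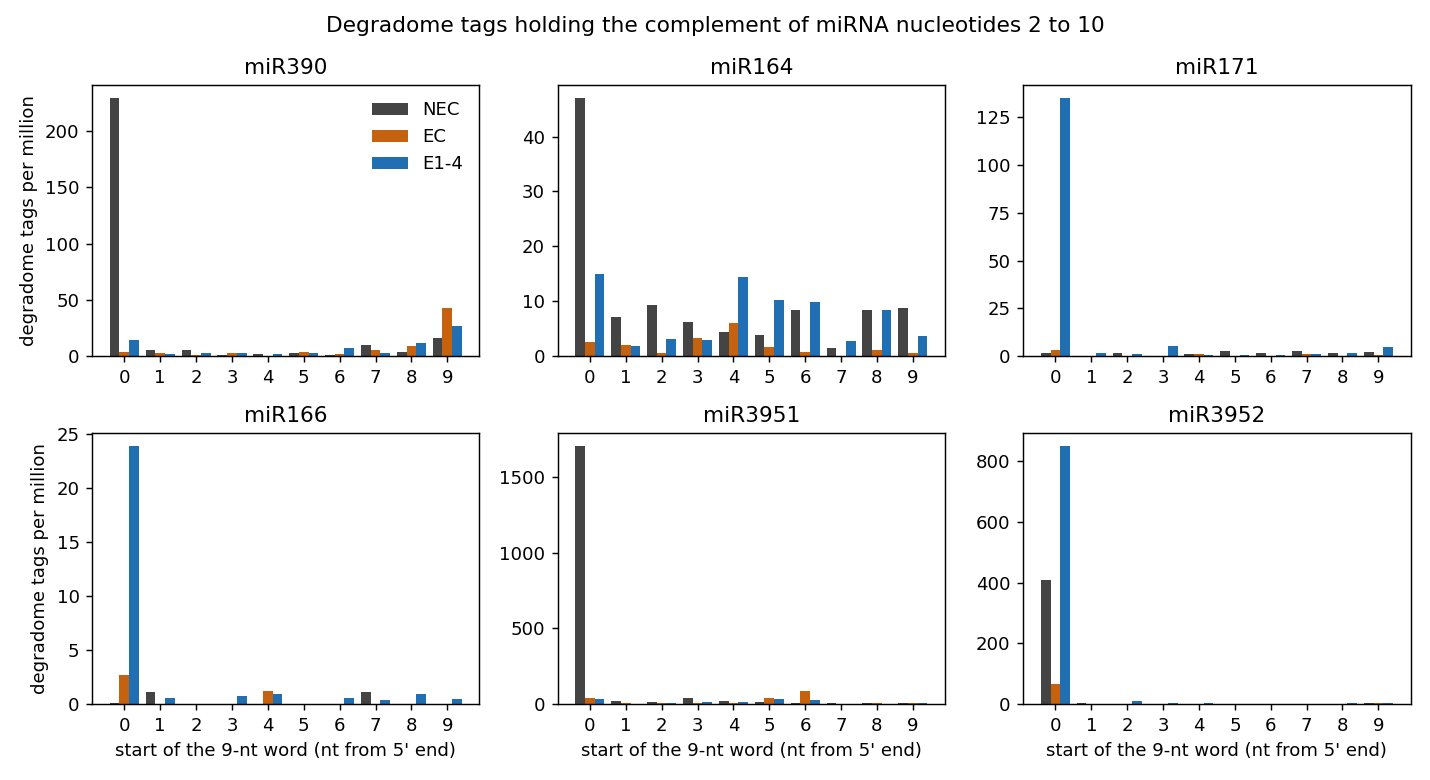
Degradome tags per 1000000 tags (bars from 0, scale set per panel) that hold the complement of miRNA nucleotides 2 to 10, by where the 9-nt word starts in the tag, in NEC, EC and E1-4. Start 0 is the expected cleavage position, where miR390 had 230 in NEC, miR164 had 47.0 in NEC, miR171 had 135 and miR166 23.9 in E1-4, miR3951 had 1704 in NEC and miR3952 had 850 in E1-4.

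The expected position held the most tags in 10 families in NEC, 10 in EC and 11 in E1-4, while each of the 9 other positions did so in at most 6, 7 and 7. Summed over the families, the expected position held 35434 tags in NEC, 2793 in EC and 14747 in E1-4, against at most 3763, 3213 and 3098 at another position, so EC had no excess there. Single families carried much of these sums, with 22460 tags of miR3951 in NEC and 9553 of miR3952 in E1-4. By distinct ends the expected position held 187, 100 and 222, against at most 137, 117 and 189 at another, a smaller excess in NEC and E1-4. In EC 1 tag of 21 nt made up 30.5% of the library, and when distinct tags were counted 5, 1 and 5 families were above background in NEC, EC and E1-4.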

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

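The tests in this part were set down before their results were seen. Sequences of 3 animal miRNAs, included as controls that a plant library should lack, were present in the callus libraries above the limit that a count of 0 allows, which was 0.149 RPM in NEC, 0.125 in EC and 0.126 in E1-4. let-7 stood at 26.1 RPM in NEC, 8.81 in EC and 7.77 in E1-4. miR-122 stood at 42.1, 8.35 and 5.38, and miR-21 at 1.93, 0.374 and 0.420. The 4 Brassicaceae controls, matched with the same limits, had 0 to 3 reads in each library.

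Chance similarity to plant sequences was tested with 100 shuffled copies of each of the 3 references. The highest exact count of a shuffled copy was 0% of the observed exact count in NEC, which was 64 reads for let-7 and 263 for miR-122. miR-21 had 0 exact reads and could not be tested this way. The test cannot decide, because random sequences hardly ever match a read exactly, whatever the origin of the reads. In the simulated data 0 of 200000 random 21-nt tags matched any family, even with mismatches allowed. Nor can shuffled copies show whether a plant sequence resembles these references. The other test asked whether animal RNA in the libraries brought further animal miRNAs along: 3 of 10 others had at least 10 exact reads in NEC (let-7f with 50, miR-143 with 33 and miR-192 with 25). That lies between the number the explanation needs, at least 5, and the number that would exclude it, at most 1. One of the 3, let-7f, is a close variant of the let-7 control, so its reads may already count there and it is not independent. Animal RNA and similarity to plant sequences therefore both stay open as possible explanations, and the level was highest in NEC for each of the 3 controls. No biological explanation was tested, since the design names none.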

How the results depend on the processing

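No paired analysis was possible because each group had 1 library and the labels give no replicate numbers. The total of all reads but miR156 and the unmatched 20 to 22 nt total were chosen after seeing the data. So were the observed sequences in the degradome and the degradome total without its 10 largest tags. The miRNA total without its largest family, miR156, was planned. Alternatives that need a genome or annotation (the genome-matched total, removal of ribosomal and transfer RNA, and those of target genes, tags per gene and origin classes) were not run. The causes of the shifts below were not tested.

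For 21-nt reads in NEC, EC and E1-4 the share was 16.7%, 10.4% and 11.4% by distinct sequences, 27.8%, 18.1% and 17.1% within 18 to 26 nt, 26.6%, 19.8% and 17.6% without miRNA reads, and 29.7%, 20.4% and 20.2% without sequences seen once. For 24-nt reads it was 40.9%, 53.3% and 47.3%, then 22.1%, 36.6% and 43.2%, then 23.2%, 48.3% and 47.3%, then 19.1%, 31.9% and 42.3%. A 5' U on 21-nt sequences had 30.03%, 34.0% and 34.0% by distinct sequences and 34.3%, 40.7% and 37.4% without miRNA reads, and a 5' A on 24-nt sequences 51.4%, 55.3% and 53.1% by distinct sequences. Shared sequences of EC and NEC, E1-4 and EC, and E1-4 and NEC were 9.24%, 12.3% and 8.003% when thinned, and 29.3%, 47.4% and 27.3% with at least 2 reads in either library.

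Families higher in EC than in NEC numbered 3 with miRNA reads as total, 11 under TMM and 8 with the unmatched 20 to 22 nt total, against 5. For E1-4 against EC, 11 were higher and 2 lower with miRNA reads as total, 10 and 5 without miR156 in that total, and 6 were lower under TMM, against 6 and 10, and 2 were higher at a minimum of 1000 reads. For E1-4 against NEC, TMM gave 8 higher and 12 lower, against 4 and 22.

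Every log2 ratio moved by 0.31, 0.34 and 0.77 for EC over NEC with miRNA reads without the largest family, reads without miR156 and unmatched 20 to 22 nt reads as total, and by -0.86, 1.05 and 0.50 for E1-4 over NEC with miRNA reads, miRNA reads without the largest family and unmatched 20 to 22 nt reads. Among families called higher or lower, the ratios that turned for EC over NEC were miR403 (0.849) and miR1515 (0.447) with miRNA reads as total, and miR827 (1.12) and miR535 (1.17) under TMM. For E1-4 over EC they were miR319 (1.09), miR162 (1.13), miR3950 (1.06) and miR3952 (1.11) with miRNA reads as total. For E1-4 over NEC they were tasiARF (1.32), miR166 (1.35), miR162 (1.29), miR1515 (1.90) and miR3950 (1.44) under TMM. Families without a call, such as miR164, miR166, miR396 and miR162 for EC over NEC and miR168, miR482 and miR827 for E1-4 over EC, also changed side under some totals. Calls gained for E1-4 over EC were miR159, miR168, miR827 and miR535 as lower with both all reads but miR156 and unmatched 20 to 22 nt reads as total, and miR171, miR396 and miR3951 as higher with miRNA reads as total. Other matching rules that moved a called ratio by over 1.5 times gave, for EC over NEC, miR319 0.0238 without mismatches and 0.0978 with the reference 5' end, and miR482 0.0966 without mismatches and 0.0992 with at most 1. For E1-4 over EC they gave miR3948 12.5 with at most 1 mismatch. For E1-4 over NEC they gave miR535 0.445 (117 against 223 reads, without its main form) and miR3950 0.595 with at most 1 mismatch, and miR3950 0.110 with the reference 5' end. They also gave miR319 0.0160 without mismatches, 0.0397 with at most 1 and 0.0319 with the reference 5' end, and without mismatches miR169 had 1 read against 1350 and miR393 1 against 1991. The report gives the other moves of miR156, miR167, miR166, miR393 and miR535. Families under 100 reads have no value without mismatches, among them miR160, miR171, miR398, miR535, miR3948 and miR3950 for EC over NEC. Of 906 family ratios over 11 alternatives, 741 kept their direction and call or moved within their interval, 34 fell under the limits, 51 passed them, 67 moved and 13 turned. The 741 include 60 of 60 and 87 of 87 under the read minimums of 1000 and 10, which leave each ratio as it was. They include 85 of 87 with the 18 to 26 nt total, which hardly differs from the main one, and 47 of 87 under TMM.

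Families above background in the degradome numbered 4 in NEC with a 10-nt word, 1 in EC and 3 in E1-4 with 1 mismatch, and 1 in EC and 5 in E1-4 by distinct tags, against 7, 4 and 8. They numbered 11 in E1-4 with the 10-nt word, and 6 in EC and 9 in E1-4 with the observed sequence. In EC 1 of the 7 control families was above with the 10-nt word and with 1 mismatch. The ratio of miR395 tags in EC to those in NEC has no value because NEC had 0 tags. Of 19 calls, each of 1 family in 1 library, 10 stayed with the 10-nt word, 7 with 1 mismatch, 10 by distinct tags and 19 with the observed sequence. Depth limits the families with few reads, such as miR160, miR393 and miR408 in EC, and the EC degradome, in which 37.2% of tags came from 10 sequences.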

Other observations

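The total without miR156 and the count of distinct 5' ends are tests chosen after the results they bear on were seen. The sequences that made up miR396, miR166 and miR156 differed between calluses, and these families were picked after their values were seen. miR396, which targets growth-regulating factors, had 423 RPM in NEC and 469 in EC, a ratio that ran from 0.218 to 3.78 over the library totals. The 21-nt form TTCCACAGCTTTCTTGAACTG made up 68.8% of it in NEC, 2.57% in EC and 1.34% in E1-4, and the 18-nt form TTCCACGGCTTTCTTGAA 12.04%, 87.05% and 88.3%. Without mismatches miR396 was lower in EC than in NEC, with a ratio of 0.0401. For miR166 the form TCTCGGACCAGGCTTCATTCC made up 56.5% in NEC and 5.26% in EC, and TCGGACCAGGCTTCATTCCCC 22.6% and 58.3%. The 20-nt form TGACAGAAGAGAGTGAGCAC made up 43.9% of miR156 in NEC, 87.1% in EC and 87.7% in E1-4.

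Several of the most abundant small RNAs, also picked after their values were seen, matched no family searched. The 19-nt GGGGATGTAGCTCAGATGG stood at 15312 RPM in NEC, 2196 in EC and 1267 in E1-4, and the 20-nt form GGGGATGTAGCTCAGATGGT at 14340.2, 3421 and 1016. Their origin was not tested, and removal of transfer RNA was not run. ATATGTAGGACTGGCTATTAA stood at 63.2 RPM in NEC, 13167 in EC and 15621 in E1-4, and TCATAGATCAAGATGACGTTT at 25.0, 7375 and 8311. ACGGGGAACAGGCAGAGCATG had 9457 in NEC, 1.50 in EC and 55.5 in E1-4. This last sequence is complementary to the main miR408 form along most of its length, as the opposite strand of a miR408 duplex would be. The miR408 family stood at 812 RPM in NEC, 0.0831 in EC and 5.17 in E1-4, in the same order. The sequence is therefore not to be read as an unknown small RNA unrelated to miR408. Small RNAs of 20 to 22 nt with at least 1000 reads in a library were grouped by their first 10 nt. This gave 845 groups, each named here by its most abundant sequence. Of these groups, 14 had degradome tags starting opposite nucleotide 10, with at least 100 tags, 3 distinct ends and 10 times the tags of each of 8 other places. In NEC 7 passed, in EC 4 and in E1-4 7, while the same rule at the other places was met by at most 2, 4 and 1, so EC had no excess. Of the 14, 7 matched a family, among them miR156 in EC with 405 tags and at most 13 at another place, and miR482 in E1-4 with 162 and at most 12. Also among them was the miR408 form TGCACTGCCTCTTCCCTGGCT in NEC, with 483 tags and 0 elsewhere, whereas the reference used above had 9 tags at the expected position and 497 at the next. The other 7 matched no family. TCAAGTGAGGTTCGGTCTTTGA had 7204 such tags in E1-4, 100 in NEC and 17 in EC, while its own level was 313 RPM in E1-4, 10264 in NEC and 1231 in EC. TCTCAGGTCGCCCCTGTGGGA had 3140 tags in NEC, 109 in EC and 599 in E1-4. It begins with the last 16 nt of the main miR398 form TGTGTTCTCAGGTCGCCCCTG, outside the 5' shift allowed, and had 579 RPM in NEC, 6.90 in EC and 27.0 in E1-4. TGATCTATGAACATATAGGCAA had 1993 in EC. In the degradome the tag CAAAACGACTCTCGGCAACGG made up 30.5% of EC, 3.59% of E1-4 and 0.00278% of NEC.

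Most miRNA families were lower in EC than in NEC (19 of 30), and miR156 alone took 218176 RPM in EC, so reads taken by miR156 are one possible explanation. Taking miR156 reads out of both totals moved every log2 ratio up by 0.34, and 100% of the 19 stayed lower. That outcome followed from the values, since the weakest of the 19, miR535, had a log2 ratio of -1.545. The size of the shift argues against reads taken by miR156 as the whole cause. For a shift between length classes, 20 to 22 nt reads of no family were the total, also chosen after the data were seen. Every log2 ratio moved up by 0.77 and 89.5% stayed lower. That too followed from the values, since only miR827, at -1.606, and miR535, at -1.545, lay close enough to the limit to lose their calls. The size of that shift argues against a shift between length classes as the whole cause. Under TMM 14 of the 19 (73.7%) stayed lower, so the number depends on the scaling. Tissue of origin, medium and age in culture differ together between NEC and EC and stay open, untested.

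Degradome 5' ends carried the word TGTANATA, known as the binding element of Pumilio proteins, 3 nt downstream, a pattern first seen by eye among the most abundant tags. It followed 777 distinct ends in NEC, 1566 in EC and 1015 in E1-4, with 1.41%, 3.02% and 0.902% of tags, and these numbers of ends were 22.7, 29.0 and 19.4 times the mean over places 5 to 10, while place 2 held 190, 462 and 366 ends. A preference for the first base in adaptor ligation is argued against by the lowest of 12 ratios by first base and library, 14.8. As to a few abundant transcripts, the lowest ratio of distinct ends was 19.4. Copies of a tag with a sequencing error count as further ends, so that ratio cannot decide. For base composition at that position, the best of 139 rearrangements of the word reached at most 0.216 of its ratio. The source of these ends stays open, and no biological explanation was tested.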
